A study of Homo sapiens with 12 samples.

How the data were processed

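RNA counts were taken from bulk libraries of microglia-like cells made from the PGP1 induced pluripotent stem cell line, in 4 groups of 3: controls and cultures given interferon gamma, fibrillar amyloid beta or TDP-43 for 24 h. Per the labels' protocols, RNA was extracted with TRIzol and a Direct-zol kit, poly(A) RNA was selected, and libraries were made with a directional NEBNext Ultra II kit. The authors deposited a table of raw counts per gene, with Ensembl gene IDs and 1 column per library. Per the submitters' processing notes, reads were aligned with STAR 2.5.2b to GRCh38. The counting tool, its strand setting and the annotation release are not given in the sources used here. The counts are whole numbers with totals of 21900066 to 25766008 per library, and all 12 columns were used.

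Of 58302 gene IDs, 57532 were named from a table of gene names and 160 from GENCODE 29, while 610, with 0.0417% of the counts, had no name. GENCODE 29 holds 58039 of the IDs, and coordinates are its GRCh38 positions, counted from 1. Genes that share reads with near-identical copies, and genes overlapped by another gene, are uncertain, since the counting rule is unknown. Genes of the Y chromosome and XIST were not reported.

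Genes were tested with the quasi-likelihood test of edgeR 4.0.16 (robust fit, TMM factors, filterByExpr on the groups) in R 4.3.3. All 12 libraries were in one fit of group means, with no other term. The 6 pairwise comparisons were read from this fit, with Benjamini-Hochberg adjustment over 18613 genes, two-sided, a threshold of 0.05 and no fold minimum. The common biological coefficient of variation was 0.0514. Mean CPM (counts scaled to a common library total) printed with fold changes used TMM-scaled library sizes. Levels of the control state, except where TMM is named, and the plots per library used raw totals. Errors are SD for levels and SE for log2 fold changes, with 3 libraries per group and 95% intervals for folds. An exact permutation test of 3 against 3 libraries cannot give a p under 0.1, so none was used for single genes. Where a group had no count of a gene, the fold was bounded by a floor of 3 counts over the group. Such floors cover counting error only. Principal components were computed on log2 CPM with a prior count of 2.

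A total of 33 gene lists was tested with camera of limma 3.58.1 with its preset correlation of 0.01, adjusted over the 33 lists within each comparison. The estimated correlation and fry were alternatives. The lists covered 6 candidate transcription factors of the cells, interferon gamma and type I interferon genes, MHC class I and II, NF-kB inflammation, the inflammasome and STING, complement, homeostatic and disease-associated microglia, myeloid genes, phagocytosis, lysosome, sterol synthesis, LXR lipid efflux, the unfolded protein response, heat shock, NRF2, p53, cell cycle, hypoxia, nuclear and mitochondrial oxidative phosphorylation, replication histones, immediate early genes, and markers of pluripotent, neural, mesenchymal, endothelial, megakaryocyte, granulocyte, endoderm and lymphoid cells. Beside each list named as past camera stands the number of members past the threshold over all genes, and the number when adjusted over the list alone.

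The groups, tests, lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule named the 8 largest rises and the 8 largest falls against the controls (5 and 5 between treatments) among genes past the threshold whose libraries did not overlap between the groups and whose mean reached 5 CPM in the higher group. It also named up to 4 members of each list past the threshold by smallest p, or else up to 2 with the highest level, and the 6 candidate factors. CXCL10, HLA-DRB1, HLA-DMA, CIITA, HLA-DRA, CD68, PTPRC, TYROBP, SLC25A6 and the genes of the control state were named after their values were seen.

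The test was first run on simulated counts drawn from the means and sizes of the real libraries, with 200 genes changed. For amyloid beta against control (18199 genes simulated), edgeR recovered 20% of genes changed by 1.25-fold, 54% at 1.5-fold, 74% at 2-fold and 90% at 4-fold. At 10 CPM or above it recovered 10 of 16, 25 of 25, 27 of 27 and 23 of 23 of them. Unchanged genes made up 4.72% to 10.2% of the calls over the 6 simulated comparisons, above the nominal 5% in most, with the highest value for TDP-43 against control.

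The 11 alternatives were DESeq2 size factors (RLE), upper-quartile factors and library size only as scalings, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0 and limma-voom as tools, only the 6 libraries compared, the replicate number as a block, a 2-fold minimum, and leaving out each library in turn. Overlap between comparisons that share the controls was set against 30 simulated draws of unchanged groups. The levels of 3 genes of the lists are not reported here. Text tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.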

Results

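The data were RNA counts from TFiMGLs, microglia-like cells made from the human induced pluripotent stem cell line PGP1 by switching on 6 transcription factors with doxycycline. The labels do not name the factors. SPI1, CEBPA, FLI1, MEF2C, CEBPB and IRF8, regulators of myeloid identity, were followed as candidates for this set. The study asked how these cells change their transcripts when they meet stimuli linked to brain inflammation and neurodegeneration. Cultures were treated for 24 h with interferon gamma, with fibrillar amyloid beta, or with TDP-43, a protein that aggregates in several neurodegenerative diseases. The form and dose of TDP-43 are not given in the sources used here. The titles abbreviate the amyloid as fAb, read here as the fibrillar form. What the control cultures received in place of a stimulus is not stated. Each of the 4 groups had 3 libraries, 12 in all. The sample titles name day 4, while the culture protocol covers day 0 to day 6. Each library held between 21900066 and 25766008 counts. The mean total was 23934824 ± 1587705 counts (SD, n = 3) in the controls and 22836655 ± 811760 counts with interferon gamma. It was 23524512 ± 602087 counts with amyloid beta and 23657897 ± 681271 counts with TDP-43. The table lists 58302 genes, of which 21000 had no count in any library and 18613 had enough counts to be tested. The labels name no sequencing batch. They also do not say whether the 3 libraries of a group came from separate cultures, so the p-values may measure technical spread alone. Spearman correlations between libraries of one group, across genes, lay between 0.990 and 0.992.

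Interferon gamma set the main axis of variation. The first principal component held 16.5% of the variance, and the interferon gamma libraries scored 27.4 to 37.7 on it, apart from the other 9, which scored -12.7 to -7.02. The second component held 11.7% and placed the TDP-43 libraries at -19.7, -4.26 and -41.5. The controls scored 8.98 to 14.7 on the second component and the amyloid beta libraries 6.69 to 8.19. On the first component the controls scored -12.7 to -11.4 and the amyloid beta libraries -10.3 to -9.47. The amyloid beta libraries thus lay next to the controls, but without overlap on either component.

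**Figure D1:**
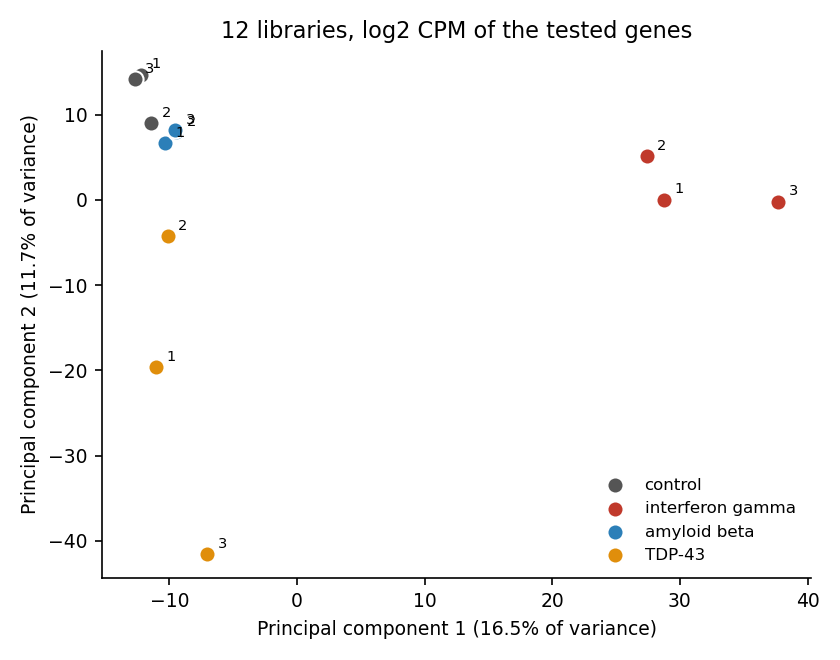
Scores of the 12 libraries on the first principal component (x axis, 16.5% of the variance) and the second (y axis, 11.7%) of log2 CPM, coloured by group, with 1 point per library. The interferon gamma libraries lie at 27.4 to 37.7 on the first component, and the TDP-43 libraries reach down to -41.5 on the second.

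In the control state some, not all, transcripts of myeloid cells and of microglia were well counted. Among general myeloid genes, LYZ (lysozyme) stood at 1576 ± 52.3 CPM (mean ± SD, n = 3), LAPTM5 at 971 ± 15.0 CPM and CYBB, the catalytic subunit of the phagocyte oxidase, at 827 ± 7.45 CPM. Of the genes used to recognise resting microglia, P2RY13 stood at 464 ± 22.2 CPM, GPR34 at 133 ± 7.42 CPM and P2RY12 at 121 ± 5.00 CPM. The receptors CSF1R and CX3CR1 were lower, at 56.0 ± 2.35 CPM and 23.6 ± 2.04 CPM. AIF1, which encodes the microglial stain IBA1, stood at 69.7 ± 3.46 CPM. Other general myeloid genes were nearly uncounted, with 7 counts of PTPRC, 3 of TYROBP and 1 of CD68 over the 3 controls. CD33 stood at 0.683 ± 0.346 CPM. Of the exons of CD68, 81.7% overlap another gene on the same strand, and reads there may not have been counted. Its count therefore does not show that the transcript was absent. Some granulocyte genes were abundant too, with S100A9 at 1276 ± 40.3 CPM and CSF3R at 1241 ± 11.0 CPM. TREM2, SALL1 and TMEM119 were scarce, at 5.78 ± 1.11 CPM, 6.86 ± 0.999 CPM and 2.75 ± 0.388 CPM. The 6 candidate factors were among the abundant transcripts, from 140.3 ± 8.74 CPM for CEBPB to 2931 ± 124 CPM (over TMM-scaled library sizes) for FLI1. These counts do not separate native from any introduced copies.

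Interferon gamma is the cytokine by which T and NK cells activate macrophages, and the comparison with the controls asked whether these cells respond to it. The antigen-transport gene TAP1 (ENSG00000168394, chromosome 6:32845209-32853978) rose to 143 ± 10.1 CPM against 4.54 ± 0.907 CPM (log2 fold change 4.97 ± 0.10 SE, n = 3 per group, edgeR adjusted p = 5.2e-61). The adhesion molecule VCAM1 (ENSG00000162692, chromosome 1:100719742-100739045) had the largest rise under the naming rule, to 20.2 ± 2.40 CPM against 0.229 ± 0.137 CPM (log2 fold change 6.39 ± 0.56, edgeR adjusted p = 2.9e-11). Its fold rests on few control counts and was 84.0-fold, 95% interval 37.3 to 189. The other 6 of the 8 largest rises, with their log2 fold changes, were SLAMF8 (5.34), GBP5 (4.75), GBP4 (4.47), BATF2 (4.24), BST2 (4.21) and PSMB9 (4.16). Canonical interferon gamma targets moved together: the guanylate-binding protein GBP1 rose to 144 ± 12.4 CPM against 9.74 ± 1.18 CPM, the tRNA synthetase WARS1 to 1018 ± 85.2 CPM against 137 ± 1.28 CPM and IRF1 to 74.6 ± 5.22 CPM against 10.8 ± 0.592 CPM. CXCL10, a T-cell attracting chemokine chosen after its values were seen, rose to 890.1 ± 91.5 CPM against 56.6 ± 2.11 CPM (log2 fold change 3.97 ± 0.06). In each gene said here to have changed in any comparison, all 3 libraries of one group lay above all 3 of the other.

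In all, 985 of 18613 genes changed with interferon gamma at an edgeR adjusted p under 0.05, 678 upward and 307 downward. Of these, 144 changed by at least 2-fold, 134 of them upward, while 750 changed by less than 1.5-fold. In 954 of the 985 the libraries of the groups did not overlap, as in 3711 of all genes tested, where chance gives 10%. The balance of directions moved with the scaling, to 513 higher and 509 lower with upper-quartile factors and to 529 and 491 with library size only. Without control replicate 1 the count was 604.

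Among the fixed gene lists, interferon programmes led. Of 39 tested genes of the interferon gamma response, 34 rose (38 when adjusted over the list alone), with a median log2 fold change of 1.68. All 34 type I interferon-stimulated genes rose, both over all genes and adjusted over the list alone, with a median of 1.37. Examples with their log2 fold changes are OAS2 (2.76), IFI6 (2.52), OAS3 (2.46) and EPSTI1 (2.28), which encode antiviral and interferon-induced proteins. Of 16 MHC class I pathway genes, 14 rose (15 adjusted over the list alone), with a median of 1.00. HLA-E rose to 294 ± 8.64 CPM against 126 ± 7.11 CPM, B2M to 885 ± 32.4 CPM against 448 ± 5.88 CPM and HLA-B to 327 ± 11.7 CPM against 175 ± 5.47 CPM, although reads of near-identical HLA genes and alleles can be exchanged between them. With an estimated correlation the camera adjusted p was 6.9e-07 for the interferon gamma response and 6.3e-07 for both other lists.

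MHC class II genes, the other antigen-presentation programme that interferon gamma raises in macrophages, did not follow. None of 8 tested members passed by edgeR, over all genes or adjusted over the list alone, and the list's camera adjusted p was 0.925. The median log2 fold change was -0.01 and the mean 0.05, with opposite signs. The invariant chain CD74 (ENSG00000019582, chromosome 5:150401637-150412929) stood at 339 ± 9.03 CPM against 349 ± 3.80 CPM (0.971-fold, 95% interval 0.926 to 1.02, edgeR adjusted p = 0.616). HLA-DPB1 stood at 47.1 ± 5.92 CPM against 43.5 ± 0.496 CPM (1.08-fold, 95% interval 0.988 to 1.19, edgeR adjusted p = 0.410). The other tested members except HLA-DRB1 had upper 95% bounds of at most 1.31-fold (HLA-DMA), while HLA-DRB1, at 1.65 ± 0.182 CPM against 1.13 ± 0.228 CPM, was too scarce to bound closely (1.46-fold, 95% interval 0.903 to 2.38). The class II transactivator CIITA, too scarce to test, had 19 counts over the 3 interferon gamma libraries and 4 over the controls.

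**Figure D2:**
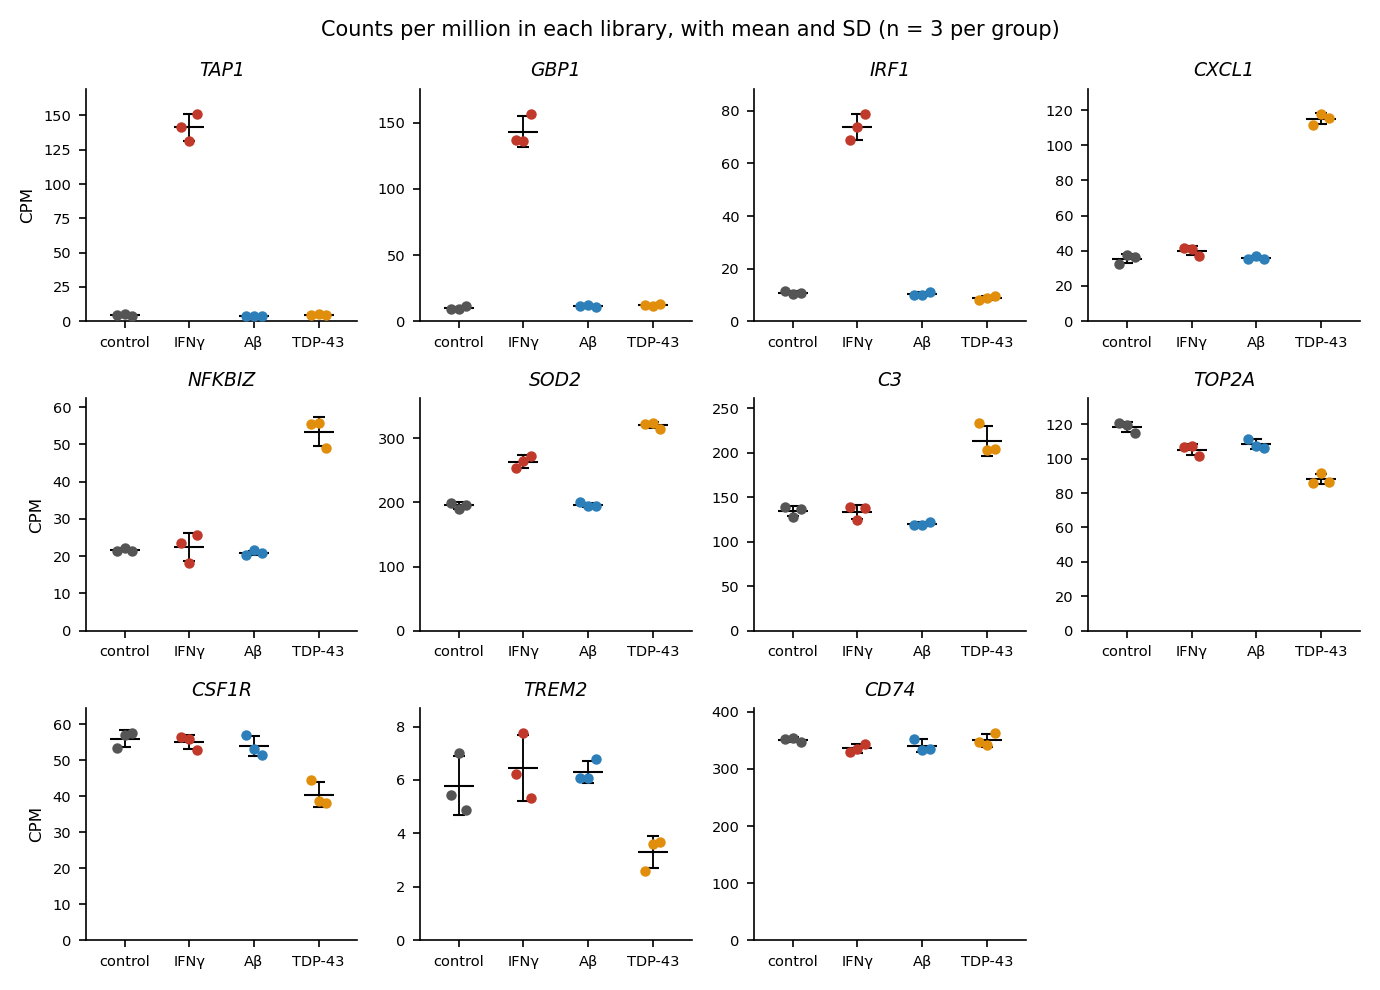
Levels in CPM over raw library totals (y axis, linear, starting at 0) of 11 genes in each library of the 4 groups (x axis), with 1 point per library and the mean and SD of 3 as bars. TAP1, GBP1 and IRF1 are high only in the interferon gamma libraries and CXCL1, NFKBIZ and C3 only in the TDP-43 libraries. The amyloid beta points lie near the controls, but for C3 and TOP2A all 3 lie below all 3 controls, without passing the threshold.

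Complement genes rose with interferon gamma as well. Of 16 tested, 6 passed (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.2e-11, 0.0011 with an estimated correlation). C1S rose to 26.9 ± 0.468 CPM against 8.85 ± 0.812 CPM and the inhibitor SERPING1 to 108 ± 11.6 CPM against 61.0 ± 2.87 CPM. C1QB, part of the C1q molecule by which microglia tag synapses, had 162 counts over the interferon gamma libraries and 0 over the controls. That is at least 56.6-fold higher, against a floor of 3 counts over the 3 control libraries. The median log2 fold change of the list was 0.26, with C1QB fitted or at that bound. The inflammasome and STING list also passed, with 4 of 14 higher (4 adjusted over the list alone), a median of 0.10 and a camera adjusted p of 2.3e-04 (0.0419 with an estimated correlation). Its members IFI16, MLKL and GSDMD rose by log2 fold changes of 0.48, 0.31 and 0.37.

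A further 5 lists passed camera with its preset correlation only. For NF-kB inflammatory genes, 4 of 27 rose (6 adjusted over the list alone; camera adjusted p = 0.0083; adjusted p = 0.0877 with an estimated correlation), namely PTGS2 (0.70), IL1B (0.52), SOD2 (0.46) and CD40 (0.45). For the unfolded protein response, 4 of 20 rose (8 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0083; adjusted p = 0.0538 with an estimated correlation), namely ATF3 (1.27), XBP1 (0.39), DNAJB9 (0.21) and HSPA5 (0.21). For lysosomal genes, 5 of 31 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0069; adjusted p = 0.474 with an estimated correlation), led by the protease CTSS (122 ± 2.97 CPM against 78.0 ± 1.27 CPM). For disease-associated microglia genes, 3 of 21 rose (5 adjusted over the list alone; camera adjusted p = 0.0295; adjusted p = 0.287 with an estimated correlation), led by the growth factor CSF1 (14.6 ± 2.17 CPM against 2.48 ± 0.310 CPM). For general myeloid genes, 6 of 19 rose (9 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.0381; adjusted p = 0.254 with an estimated correlation), CYBB by 0.24 and FCGR2A by 0.35. The camera call was lost for the unfolded protein response without interferon gamma replicate 1 (0.0549). It was lost for disease-associated genes without control replicate 1 (0.0779) or interferon gamma replicate 2 (0.0750), and for myeloid genes without control replicate 1 (0.0515) or interferon gamma replicate 1 (0.114). With upper-quartile factors or library size only, 1 gene of the unfolded protein response, 1 of complement and 2 myeloid genes also passed downward.

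The decreases with interferon gamma that the naming rule picks were small, while 10 of the 307 lower genes fell by 2-fold or more. The kinase gene ALPK1 fell to 35.0 ± 1.88 CPM against 54.8 ± 4.04 CPM (log2 fold change -0.65 ± 0.07, edgeR adjusted p = 7.0e-13), and fatty acid synthase FASN to 53.1 ± 2.72 CPM against 73.7 ± 2.61 CPM (-0.47 ± 0.06, edgeR adjusted p = 4.3e-10). NAV1, the long noncoding RNA PURPL and the pseudogene ANKRD20A11P fell, with log2 fold changes of -0.52, -0.47 and -0.45; reads of that pseudogene can be shared with its copies. MSANTD2, ZC3HAV1L and ANKRD36C completed the 8 largest falls, and each lost its edgeR call when 1 library was left out. For MSANTD2 (-0.53) the adjusted p became 0.107 or 0.0536 without control replicate 1 or 2 and 0.181 or 0.0517 without interferon gamma replicate 1 or 2. For ZC3HAV1L (-0.45) it became 0.0760, 0.154 or 0.0913 without control replicate 1, 2 or 3 and 0.0852 or 0.215 without interferon gamma replicate 1 or 3. With DESeq2 the adjusted p of ZC3HAV1L was 0.0544. For ANKRD36C (-0.44) it became 0.0665 or 0.0550 without control replicate 1 or 3. The lipoprotein receptor LRP1, MYC and the sterol enzyme LSS fell as well, with log2 fold changes of -0.44, -0.40 and -0.27. The sterol synthesis list as a whole did not pass, with 4 of 20 lower (5 adjusted over the list alone) and a camera adjusted p of 0.0698. None of the 6 candidate factors passed by edgeR, and the largest log2 fold change among them was 0.05 (SPI1).

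Fibrillar amyloid beta is the material of plaques in Alzheimer's disease, and its comparison with the controls asked whether the cells react to it within 24 h. No gene passed an adjusted p of 0.05 with edgeR, and DESeq2 and limma-voom also called 0. Of 18613 genes, 1001 (5.38%) had an unadjusted p under 0.05, and the smallest edgeR adjusted p was 0.220. The intervals left little room for large changes in well-counted genes. Of 9595 genes at 10 CPM or above, 99.9% had a 95% fold interval inside 1.5-fold either way. EdgeR called 10 genes with only the 6 libraries compared, 4 without the filter on low counts, 2 with the replicate number as a block and 2 without control replicate 3. The libraries of the groups did not overlap in 2215 of the 18613 genes, where chance gives 10%.

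Some abundant members of the gene lists had narrow intervals near the controls with amyloid beta. APOE stood at 37.2 ± 1.66 CPM against 36.2 ± 3.16 CPM (1.03-fold, 95% interval 0.929 to 1.13). The cathepsin gene CTSB stood at 714 ± 8.82 CPM against 692 ± 9.96 CPM (1.03-fold, 95% interval 0.991 to 1.08). SOD2 stood at 195 ± 2.90 CPM against 194 ± 5.03 CPM (1.01-fold, 95% interval 0.958 to 1.06). MYC, by contrast, lay lower without passing, at 136 ± 7.97 CPM against 162 ± 13.8 CPM (log2 fold change -0.25 ± 0.06, edgeR adjusted p = 0.487). Over the lists no member passed over all genes tested, but scarce members were not bounded closely: log2 fold changes ran from -0.47 to 0.78 among disease-associated microglia genes. Adjusted over the list alone, 1 gene was lower in each of the complement, phagocytosis, hypoxia and immediate early lists. In the interferon gamma response and lymphoid lists 1 gene each was higher. Camera passed 2 of 33 lists, each lost with an estimated correlation. Sterol synthesis lay lower, with a median log2 fold change of -0.06, 1 lower gene adjusted over the list alone and a camera adjusted p of 0.0151 (adjusted p = 0.627 with an estimated correlation). Endoderm and trophoblast markers lay higher, with a median of 0.40 over 7 scarce genes, 0 adjusted over the list alone and a camera adjusted p of 0.0151 (adjusted p = 0.424 with an estimated correlation). The sterol call was lost without control replicate 3 (0.113) or amyloid beta replicate 2 (0.134). The endoderm call was lost without control replicate 1 or 3 (0.0733 or 0.0887) or amyloid beta replicate 2 or 3 (0.134 or 0.0683).

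**Figure D3:**
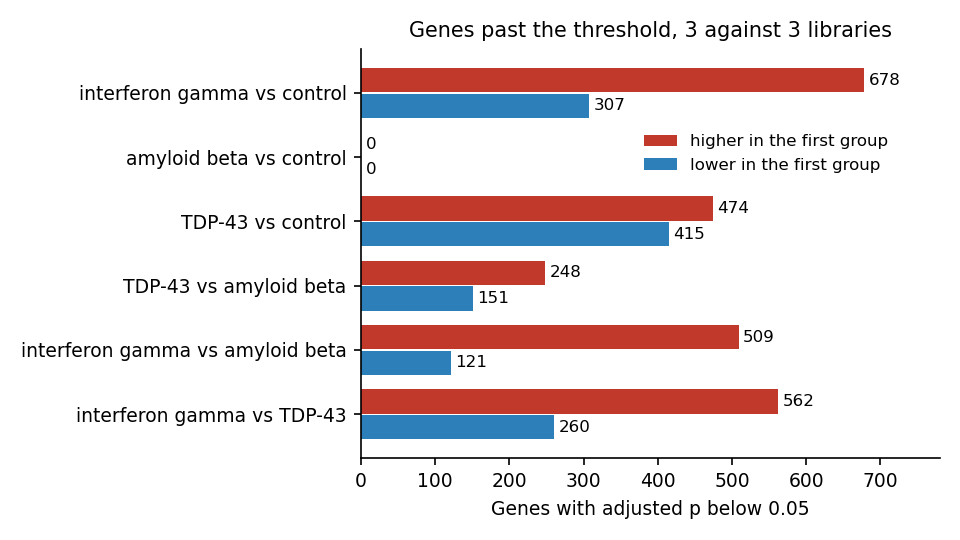
Number of genes with an edgeR adjusted p under 0.05 (x axis) in each of the 6 comparisons (y axis), as bars for genes higher and lower in the first group, 3 libraries against 3. Interferon gamma and TDP-43 changed 985 and 889 genes against the controls, and amyloid beta changed 0.

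Genes of the NF-kB inflammatory list rose in the cultures given TDP-43. What the controls received is not stated, so effects of the protein and of its preparation cannot be told apart. The neutrophil chemokine CXCL1 (ENSG00000163739, chromosome 4:73869393-73871242) rose to 116 ± 3.36 CPM against 35.3 ± 2.55 CPM (log2 fold change 1.72 ± 0.06, n = 3 per group, edgeR adjusted p = 8.7e-40). The NF-kB cofactor NFKBIZ (ENSG00000144802, chromosome 3:101827991-101861022) rose to 53.9 ± 3.62 CPM against 21.6 ± 0.429 CPM (1.32 ± 0.08, edgeR adjusted p = 2.8e-23), and mitochondrial superoxide dismutase SOD2 to 323 ± 2.94 CPM against 194 ± 5.03 CPM (0.74 ± 0.04, edgeR adjusted p = 2.7e-29). The other 6 of the 8 largest rises were ANKRD26P1 (1.70), RELN (1.15), HAVCR2 (1.04), TNIP3 (1.01), FOS (0.98) and CCL20 (0.90); ANKRD26P1 is a pseudogene whose reads can be shared with its parent gene. Of 27 tested NF-kB inflammatory genes, 12 rose (12 adjusted over the list alone), with a median log2 fold change of 0.38. The list's camera adjusted p was 1.3e-41, and 3.5e-05 with an estimated correlation. PTGS2, which encodes cyclooxygenase-2, rose to 72.2 ± 1.70 CPM against 48.9 ± 4.09 CPM, and IL1B to 59.5 ± 2.75 CPM against 45.4 ± 4.45 CPM.

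Proliferation genes fell with TDP-43. Of 33 cell cycle genes, 17 fell and 0 rose (26 lower adjusted over the list alone), with a median log2 fold change of -0.31. The camera adjusted p was 1.9e-26, and 6.3e-04 with an estimated correlation. The topoisomerase TOP2A fell to 88.8 ± 2.96 CPM against 117 ± 2.70 CPM (log2 fold change -0.40 ± 0.05, edgeR adjusted p = 1.4e-10), and the proliferation marker MKI67 to 71.9 ± 4.26 CPM against 91.7 ± 3.46 CPM. The replication clamp PCNA and the spindle motor KIF11 each fell as well, with log2 fold changes of -0.32 and -0.32. IQGAP3 and POLQ, which dividing cells also express, were among the 8 largest falls, at -0.93 and -0.68. EPPK1, FCN1, TMEM273 and ARHGDIB also fell, with log2 fold changes of -0.85, -0.80, -0.77 and -0.68.

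Some microglial receptors fell with TDP-43, while other genes of microglia and myeloid cells rose. CSF1R, the receptor for the survival factor CSF1, fell to 40.8 ± 3.32 CPM against 55.6 ± 2.34 CPM (log2 fold change -0.44 ± 0.06, edgeR adjusted p = 2.4e-07), and the purinergic receptor P2RY12 to 102 ± 3.72 CPM against 120.1 ± 5.09 CPM (-0.24 ± 0.04, edgeR adjusted p = 1.8e-04). TREM2, a lipid receptor tied to Alzheimer risk, fell to 3.32 ± 0.624 CPM against 5.73 ± 1.09 CPM (-0.79 ± 0.18, edgeR adjusted p = 0.00320). Its edgeR adjusted p was 0.0679 without control replicate 2 and 0.0561 without TDP-43 replicate 1. LRP5L, also among the 8 largest falls (-0.68, edgeR adjusted p = 0.0216), lost its call without control replicate 1 (0.127) or 2 (0.0904) and without TDP-43 replicate 1 (0.0771) or 3 (0.0810). The fall of CX3CR1 (-0.34, edgeR adjusted p = 0.0129) lost its call without control replicate 2 (0.132) and without TDP-43 replicate 2 (0.0591) or 3 (0.0716). The phagocytic receptors LRP1 (-0.36) and STAB1 (-0.24) fell, while HAVCR2 (1.04) and CD14 (0.31) rose. The homeostatic microglia list as a whole did not pass camera, with 1 higher and 3 lower of 18 (2 and 3 adjusted over the list alone) and a camera adjusted p of 0.220. Nor did disease-associated microglia genes, with 3 higher and 1 lower of 21 (4 and 2 adjusted over the list alone; camera adjusted p = 0.220), or general myeloid genes, with 5 higher and 0 lower of 19 (5 and 0 adjusted over the list alone; camera adjusted p = 0.115). By the alternative test fry, the homeostatic list did pass, downward (fry adjusted p = 0.0280).

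Some genes of the complement, lysosome and NRF2 lists also rose with TDP-43. Complement component C3 rose to 216 ± 16.3 CPM against 134 ± 5.75 CPM (log2 fold change 0.69 ± 0.04, edgeR adjusted p = 9.3e-21), and the complement regulators CD55 and CD59 rose by 0.20 and 0.24. The complement list had 3 of 16 higher (4 adjusted over the list alone), a median of 0.14 and a camera adjusted p of 4.0e-05, and 0.0198 with an estimated correlation. CTSS rose to 132 ± 2.16 CPM against 78.0 ± 1.27 CPM and CTSB by 0.15; the lysosome list had 5 of 31 higher (6 adjusted over the list alone; camera adjusted p = 1.4e-08; adjusted p = 0.136 with an estimated correlation). The iron store FTH1 and the NADPH enzyme ME1 rose by 0.17 and 0.27, and the NRF2 list had 4 of 15 higher (8 adjusted over the list alone; camera adjusted p = 4.0e-05; adjusted p = 0.0874 with an estimated correlation). MSMO1 of sterol synthesis rose by 0.19, and that list had 4 of 20 higher (6 adjusted over the list alone; camera adjusted p = 2.8e-04; adjusted p = 0.144 with an estimated correlation). Among the candidate factors, FLI1 rose to 3327 ± 83.8 CPM against 2931 ± 124 CPM and SPI1 to 1036 ± 14.3 CPM against 926 ± 39.7 CPM. Of the 6, 4 passed (5 adjusted over the list alone; camera adjusted p = 2.3e-06; adjusted p = 0.144 with an estimated correlation). Of the other 2 calls, MEF2C (0.13) had an adjusted p of 0.0970 with limma-voom, and CEBPB (0.15) lost its edgeR call under 2 scalings (0.0575 with upper-quartile factors, 0.0886 with library size only). It also lost it without control replicate 1 (0.291), control replicate 3 (0.0711) or TDP-43 replicate 1 (0.193).

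Interferon genes moved little with TDP-43. Of 39 interferon gamma response genes, 8 rose (13 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0038; adjusted p = 0.318 with an estimated correlation), with a median of 0.04. They included ICAM1 (0.83) and SOCS3 (0.77), which NF-kB and STAT3 also induce, and LAP3 (0.26). Of 34 type I interferon genes, 1 rose (1 adjusted over the list alone; camera adjusted p = 0.502). The interferon gamma response had 5 higher with upper-quartile factors and 5 higher and 1 lower with library size only, where the type I list had 0 higher and 1 lower. Of 16 MHC class I genes, 3 rose (5 adjusted over the list alone; camera adjusted p = 0.0203; adjusted p = 0.237 with an estimated correlation), with B2M at 0.26 and HLA-B at 0.23. The median of that list was 0.01, and it turned negative with upper-quartile factors (-0.00) and with library size only (-0.02). Hypoxia and glycolysis genes had 3 of 26 higher, among them ADM at 0.64 (5 adjusted over the list alone; camera adjusted p = 0.0241; adjusted p = 0.237 with an estimated correlation). Nuclear and mitochondrial genes of oxidative phosphorylation had medians of 0.06 and 0.10 with 0 members past the threshold, also adjusted over the list alone. Their camera adjusted p values were 0.0183 and 0.0090, with adjusted p = 0.449 and adjusted p = 0.470 with an estimated correlation. These list calls were lost without 1 library. MHC class I lost it without control replicate 3 (0.0790) or TDP-43 replicate 1 (0.0503) and hypoxia without control replicate 3 (0.0623) or TDP-43 replicate 1 (0.0700). Both oxidative phosphorylation lists lost it without TDP-43 replicate 3 (0.197 for nuclear and 0.240 for mitochondrial genes).

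In all, 889 genes changed with TDP-43 at an edgeR adjusted p under 0.05, 474 upward and 415 downward. Most changes were small: 28 reached 2-fold, 12 upward and 16 downward, and 803 stayed under 1.5-fold. In 841 of the 889 the libraries did not overlap, as in 3695 of all genes tested, where chance gives 10%. The directions became 361 higher and 458 lower with upper-quartile factors and 302 and 568 with library size only. The count was 450 without control replicate 1 and 474 without TDP-43 replicate 3. That library stood apart: 4.53% of its counts were mitochondrial, against 3.54% to 4.13% in the other 11, its 10 most abundant genes held 5.24% of the counts, and it had the fewest genes with a count (25666).

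**Figure D4:**
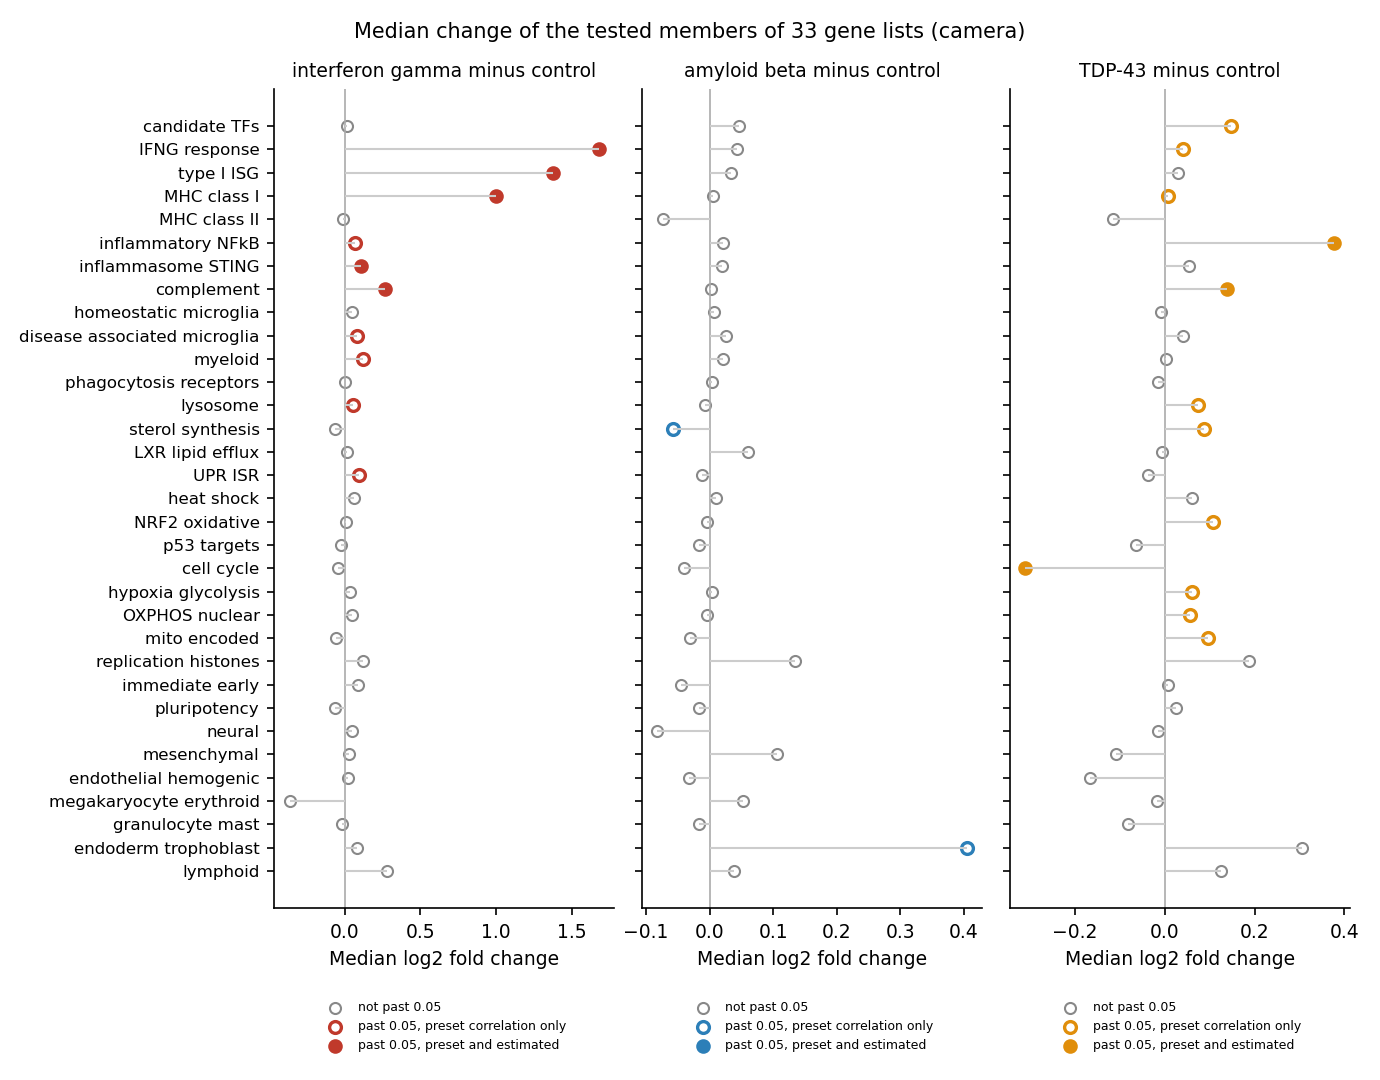
Median log2 fold change against the controls (x axis, a scale of its own in each panel) of the tested members of 33 gene lists (y axis) with interferon gamma, amyloid beta and TDP-43. Filled points passed camera with the preset and the estimated correlation, coloured open points with the preset only and grey points not; interferon lists reach 1.68 with interferon gamma and NF-kB genes 0.38 with TDP-43.

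For 15 of the 33 lists, camera passed in none of the 3 comparisons with the controls. Besides MHC class II and homeostatic microglia, whose lowest adjusted p values over the 3 comparisons were 0.292 and 0.220, these were phagocytosis receptors (0.784), genes of lipid efflux driven by LXR (0.335), heat shock genes (0.151), p53 targets (0.122), replication histones (0.12) and immediate early genes (0.119). Single members moved all the same, in both directions. Of the immediate early genes, JUN and ATF3 rose by 0.98 and 1.27 with interferon gamma and MYC fell (-0.40). Of 18 p53 targets, CDKN1A (0.25) rose with interferon gamma, while MDM2 (-0.13), TP53INP1 (-0.21) and ZMAT3 (-0.20) fell. With TDP-43, 0 rose, MDM2 (-0.14) and TP53INP1 (-0.25) fell, and ZMAT3 (-0.16) passed the threshold with overlapping libraries. These falls were fragile except that of ZMAT3 with interferon gamma: TP53INP1 lost its edgeR call without control replicate 1 in both comparisons (0.468 and 0.217), MDM2 without replicate 3 of either treatment (0.0687 and 0.111) and ZMAT3 without TDP-43 replicate 3 (0.479). With only the 6 libraries compared, the edgeR adjusted p with TDP-43 was 0.0520 for TP53INP1 and 0.268 for ZMAT3. Markers of other cell types were also among them, with lowest adjusted p values of 0.335 for pluripotency, 0.916 for neural, 0.488 for mesenchymal, 0.112 for endothelial and hemogenic, 0.0820 for megakaryocyte and erythroid, 0.220 for granulocyte and mast cell and 0.326 for lymphoid genes. Fry passed some of these 15 lists, among them homeostatic microglia, as given below.

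Direct comparison of the treatments separated the interferon response from part of the NF-kB list. Other genes of that list, among them SOD2, PTGS2 and IL1B, rose against the controls with both treatments. Against TDP-43, interferon gamma changed 822 genes by edgeR, 562 higher and 260 lower, with 143 at 2-fold or more (126 and 17). The largest differences upward, as log2 fold changes, were VCAM1 (5.28), GBP5 (5.18), TAP1 (4.94), GBP4 (4.85) and SLAMF8 (4.59). The largest downward were CXCL1 (-1.53), NFKBIZ (-1.25), CCL20 (-1.12) and TNIP3 (-1.03), with ANKRD26P1 at -1.30 (edgeR adjusted p = 9.0e-04, DESeq2 adjusted p = 0.0590). Lists higher with interferon gamma, at adjusted p = 8.7e-07 with an estimated correlation, were the interferon gamma response (31 of 39 genes), type I interferon genes (32 of 34) and MHC class I (15 of 16). Adjusted over the list alone, 36, 34 and 15 of their genes were higher and 1, 0 and 0 lower. Cell cycle genes were higher too (10 of 33, adjusted p = 0.0096 with an estimated correlation), while NF-kB genes (8 lower and 1 higher of 27, adjusted p = 0.0015) and sterol synthesis (9 lower of 20, adjusted p = 0.0379) were lower. Adjusted over the list alone, these were 28 higher cell cycle genes, 8 lower and 2 higher NF-kB genes and 12 lower sterol genes. Of 12 lists past camera, 7 held with an estimated correlation, complement being the other one (6 higher and 2 lower of 16, and 6 and 3 adjusted over the list alone; adjusted p = 0.0293). With upper-quartile factors the directions were 507 higher and 354 lower.

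TDP-43 and amyloid beta, both proteins that aggregate in neurodegeneration, also differed from each other. By edgeR, 399 genes changed, 248 higher and 151 lower with TDP-43, of which 16 reached 2-fold (10 and 6). The leading rises were ANKRD26P1 (2.36), CXCL1 (1.70), NFKBIZ (1.37), CSF3 (1.21) and RELN (1.18), and the leading falls IQGAP3 (-0.94), TREM2 (-0.92), TMEM273 (-0.86), PYCARD (-0.80) and FCN1 (-0.75). NF-kB genes were higher (10 of 27, adjusted p = 1.8e-05 with an estimated correlation) and cell cycle genes lower (11 of 33, adjusted p = 0.0010), and sterol synthesis genes were higher (7 of 20, adjusted p = 0.0162). Adjusted over the list alone, these were 13, 22 and 11 genes. Of 12 lists past camera, 5 held with an estimated correlation, the other two being complement (3 of 16 higher, and 4 higher and 1 lower adjusted over the list alone; adjusted p = 0.0145) and NRF2 (4 of 15 higher, and 9 adjusted over the list alone; adjusted p = 0.0296). The count depended on single libraries: it was 226 or 211 without amyloid beta replicate 1 or 2 and 255 or 235 without TDP-43 replicate 1 or 3. The directions were 194 higher and 183 lower with upper-quartile factors and 158 and 240 with library size only.

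Interferon gamma also differed from amyloid beta. By edgeR, 630 genes changed, 509 higher and 121 lower, of which 117 reached 2-fold (113 and 4). The leading rises were VCAM1 (6.06), SLAMF8 (5.86), TAP1 (5.20), PSMB9 (5.06) and BATF2 (4.35). ALPK1 and AADACL3 were lower, at -0.59 and -0.54. The interferon gamma response (33 of 39 genes higher), type I interferon genes (32 of 34) and MHC class I genes (13 of 16) each reached adjusted p = 5.3e-07 with an estimated correlation, and 37, 34 and 15 genes passed adjusted over the list alone. Of 10 lists past camera, 6 held with an estimated correlation. The others were complement (7 of 16 higher, adjusted p = 8.5e-04), the inflammasome and STING list (5 of 14 higher) and the unfolded protein response (4 of 20 higher), both at adjusted p = 0.0258. Adjusted over the list alone, these were 8 higher and 1 lower, 5 higher, and 9 higher and 2 lower. The directions were 416 higher and 222 lower with upper-quartile factors and 438 and 192 with library size only.

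Interferon gamma and TDP-43 also shared part of their changes. By edgeR, 262 genes changed in the same direction in both comparisons with the controls, 152 upward and 110 downward, and 11 changed in opposite directions. Independent lists of these sizes would share 17.3 upward and 6.84 downward. Simulated unchanged groups set against the same controls shared 0 in each of 30 draws, but at most 2 genes were called there in any comparison, so this 0 does not gauge the overlap of long lists. Examples shared upward are SOD2, PTGS2, IL1B, CTSS, XBP1 and FTH1, and LRP1 was shared downward. Across 9603 genes at 10 CPM or above, which are not independent replicates, the log2 fold changes correlated at a Pearson r of 0.357, against 0.496 in the simulation. Their covariance was 0.0086 against 0.0027 simulated, a difference of 0.0059. The covariance differences for the pairs with amyloid beta were 0.0021 with interferon gamma (Pearson r 0.319 against 0.497 simulated) and 0.0016 with TDP-43 (0.460 against 0.498). The 3 controls cannot be divided into sets of at least 2, so part of the overlap may come from the shared controls. The libraries of both treatments also had fewer genes with a count, 26162 ± 168 with interferon gamma and 26042 ± 351 with TDP-43, against 26810 ± 300 in the controls and 26816 ± 249 with amyloid beta (SD, n = 3). Their counts came on average from slightly shorter genes. The mean log10 exon length was 3.7511 ± 0.0024 and 3.7507 ± 0.0051 against 3.7567 ± 0.0028 and 3.7557 ± 0.0012. TDP-43 replicate 2, at 3.7552, lay within the controls' range of 3.7548 to 3.7599. These differences in genes counted and in length were not separated from the shared change. Without control replicate 1 the overlap was 103, and without TDP-43 replicate 3 it was 141. Its directions were 92 upward and 154 downward with upper-quartile factors, 90 and 174 with library size only and 116 and 120 without the filter on low counts.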

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

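Counts of changed genes and the genes named by the rule were recomputed under each alternative that applies to them, and no named gene changed sign. List calls against the controls were recomputed with an estimated correlation, fry, limma-voom values, the replicate block and 1 library left out, and none changed direction; they were not repeated under other scalings, filters or DESeq2. The balance of directions did turn with library size only, from 474 higher and 415 lower to 302 and 568 with TDP-43 and from 248 and 151 to 158 and 240 for TDP-43 against amyloid beta. With TDP-43 it also turned to 361 and 458 with upper-quartile factors, to 379 and 400 without the filter on low counts and to 506 and 518 without TDP-43 replicate 2. For the overlap of interferon gamma and TDP-43, 152 upward and 110 downward became 92 and 154 with upper-quartile factors, 90 and 174 with library size only and 116 and 120 without the filter. The counts of changed genes stayed within 1.5 times their value under other scalings, filters and tools, and with only the 6 libraries compared, except for amyloid beta. With amyloid beta, 0 genes became 4 without the filter on low counts and 10 with only the 6 libraries compared, so its overlap with interferon gamma became 4 and 8 and that with TDP-43 became 2 and 3. A 2-fold minimum left 144 genes with interferon gamma, 28 with TDP-43, 16 for TDP-43 against amyloid beta, 117 for interferon gamma against amyloid beta, 143 for interferon gamma against TDP-43, and 3 in the overlap of interferon gamma and TDP-43. The minimum itself removes genes of smaller change; the cause of the other shifts was not tested.

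Leaving out 1 library at a time gave 604 to 893 genes with interferon gamma, 450 to 1024 with TDP-43 and 0 to 2 with amyloid beta. It gave 211 to 540 for TDP-43 against amyloid beta, 449 to 619 for interferon gamma against amyloid beta and 647 to 738 for interferon gamma against TDP-43. The overlap of interferon gamma and TDP-43 ranged from 103 to 284, and both overlaps with amyloid beta from 0 to 2. The lowest values for interferon gamma (604), TDP-43 (450) and their overlap (103) came without control replicate 1, and without TDP-43 replicate 3 the last 2 were 474 and 141. For TDP-43 against amyloid beta the count was 226 or 211 without amyloid beta replicate 1 or 2 and 255 or 235 without TDP-43 replicate 1 or 3. Amyloid beta reached 2 genes without control replicate 3. Of the named genes, 27 of 84 with interferon gamma and 30 of 82 with TDP-43 lost their call without at least 1 library. Under any 1 other scaling, filter or tool, at most 8 lost it with interferon gamma (upper-quartile factors). With TDP-43 at most 10 lost it (library size only).

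Of the list tests, 24 passed in the 3 comparisons with the controls. With an estimated correlation 8 passed, with fry 26, with camera on limma-voom values 29 and without 1 library 22 to 26. The 26 with fry leave out 5 of the 24: sterol synthesis (0.541) and endoderm and trophoblast markers (0.523) with amyloid beta, and with TDP-43 the interferon gamma response (0.0943) and nuclear (0.223) and mitochondrial (0.256) oxidative phosphorylation genes. They include lists that camera did not pass. Among these, homeostatic microglia lay higher with interferon gamma (fry adjusted p = 0.0038) and lower with TDP-43 (0.0280). With interferon gamma, phagocytosis receptors (0.0478) and endothelial and hemogenic genes (0.0338) also passed fry upward, and pluripotency genes (0.0478) downward.

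The replicate numbers were not shown to pair the libraries, but pairing stays open. The share of mitochondrial ribosomal RNA rose from replicate 1 to 2 to 3 in every group. From replicate 1 to 3 it went from 1.20% to 1.39% in the controls and from 1.22% to 1.40% with interferon gamma. With amyloid beta it went from 1.28% to 1.33%, and with TDP-43 from 1.27% to 1.54%. Correlations over genes showed no pairing. Deviations of same-numbered libraries from their group means correlated between -0.0272 and 0.0246 in 18 pairs, where each would need to exceed 0.1, against -0.0326 to 0.0236 in 36 pairs of different numbers. With the replicate number as a block, the counts were 1058 with interferon gamma, 996 with TDP-43, 456 for TDP-43 against amyloid beta, 674 for interferon gamma against amyloid beta, 887 for interferon gamma against TDP-43 and 304 in the overlap of interferon gamma and TDP-43. Amyloid beta had 2, its overlap with interferon gamma 2 and with TDP-43 1, and 24 list tests passed. Depth limits scarce genes: in simulated counts few small changes below 10 CPM were recovered.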

Other observations

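The tests of depth, of an outlying library, of the interferon response, of CD74 reads, of CIITA, of overlapping exons and of pseudoautosomal genes were chosen after the results were seen.

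The control libraries also held transcripts of genes listed here as markers of other cell types. Bulk counts cannot tell whether the microglia-like cells or other cells in the cultures carried them. Of granulocyte genes, S100A9 stood at 1276 ± 40.3 CPM, the G-CSF receptor CSF3R at 1241 ± 11.0 CPM and CAMP at 263 ± 16.2 CPM, while the primary granule enzyme ELANE had 0 counts in the controls, which allows up to 0.0418 CPM. Of pluripotency genes, L1TD1 stood at 732 ± 22.8 CPM and POU5F1 at 126 ± 4.58 CPM, but NANOG and SOX2 only at 1.61 ± 0.278 CPM and 0.936 ± 0.0990 CPM. The endothelial receptor KDR stood at 189.8 ± 3.91 CPM and the platelet chemokine PPBP at 88.0 ± 3.98 CPM. PPBP rose with interferon gamma and with TDP-43, by 0.21 and 0.31 on the log2 scale, and the endothelial PECAM1 rose with interferon gamma by 0.33 but fell with TDP-43, with a log2 fold change of -0.17. KDR, L1TD1 and POU5F1 rose with TDP-43, by log2 fold changes of 0.13, 0.12 and 0.15. Each of these 4 calls with TDP-43 was lost without control replicate 1, at edgeR adjusted p = 0.126, 0.127, 0.147 and 0.167, and each was lost without at least 1 other library. With library size only the rises of KDR, L1TD1 and POU5F1 had adjusted p = 0.101, 0.0644 and 0.0645, and that of KDR had 0.0597 with upper-quartile factors and 0.0803 without the filter on low counts.

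Amyloid beta left no gene past the threshold, although 10 passed with only the 6 libraries compared, 4 without the filter on low counts and 2 with the replicate block. For well-counted genes, a lack of depth that hid changes of 1.5-fold or more is argued against. Of genes at 10 CPM or above, 99.9% had a 95% interval inside 1.5-fold either way. That share was also 98.1% with interferon gamma and 99.1% with TDP-43, where 985 and 889 genes passed. It therefore says nothing on changes under 1.5-fold, which made up most of the calls there. An outlying amyloid beta library is argued against as well, since leaving out any one of them gave 0 genes. What stays open is whether the fibrils reached the cells in an active form, whether 24 h was the right time, and changes in scarce genes or of small size. A weak reaction to this preparation may be biological, but no other dose or time was measured, and the 0 genes cannot separate an inactive stimulus from an unresponsive cell.

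MHC class II genes did not rise with interferon gamma. A failed treatment is argued against, since 14 of 16 tested MHC class I genes rose. Reads of CD74 lost to an overlapping gene are argued against too. Of its exons, 0% overlap another gene on its strand, and the control libraries held 347 to 354 CPM of it. The upper 95% bound of its fold, 1.02, is the pattern itself and cannot test this. Reads lost among the HLA class II genes were not tested. Little transcript of the transactivator CIITA is a candidate explanation. CIITA had 19 counts with interferon gamma and 4 in the controls, 1 with amyloid beta and 0 with TDP-43. Its counts were thus higher with interferon gamma, at a mean of only 0.0853 CPM over all 12 libraries. They were too few for the edgeR test and fell short of the number asked here to bound the rise, so the explanation stays open. HLA-DRA was near the floor in every group, with 2 counts in the controls and 7 with interferon gamma. No biological explanation could be tested within this design.

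Some genes of the myeloid lineage were almost uncounted. CD68 (chromosome 17:7579467-7582113) had 3 counts in 12 libraries, PTPRC, which encodes CD45, 7 in the controls and 35 with interferon gamma, and TYROBP, the adaptor of TREM2, 3 in the controls. A rule that drops reads in exons shared by overlapping genes may explain CD68. Of its exons, 81.7% overlap another gene on the same strand, and of the 315 protein-coding genes overlapped over 75% and under 100%, 71.1% lay under 0.05 CPM, against 18.3% of 16455 genes without overlap. Of 244 genes wholly overlapped, 98.8% lay under that level, while CYP51A1, overlapped by 79.4%, kept 1.87 CPM. Reads of genes in the pseudoautosomal region also went missing, with 16 of 18 protein-coding genes there at no count, among them SLC25A6. The rule is argued against for PTPRC and TYROBP, whose same-strand overlap was 0%, and the reason for their scarcity stays open, with no biological explanation tested.

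With 3 against 3 libraries there are 10 splits, so the share of splits with as many genes cannot fall under 0.1. For interferon gamma the real split gave 985 genes and the highest other 1, and for TDP-43 889 and 23. For TDP-43 against amyloid beta the values were 399 and 0, for interferon gamma against amyloid beta 630 and 0, and for interferon gamma against TDP-43 822 and 5. For each of these 5 comparisons 1 of 10 splits gave as many genes. For amyloid beta the real and the highest other split both gave 0, so 10 of 10 gave as many.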
